A study of Bos taurus with 14 samples.

How the data were processed

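RNA was measured in longissimus dorsi muscle of 14 female cattle at postnatal day 485, 7 from control and 7 from restricted dams, with groups taken from the treatment label of each sample. Replicate numbers follow the order of the samples and pair nothing. The sample titles also carry a first letter (R or Y) and a last letter (A or B) whose meaning the labels do not give. They were used only as covariates or to choose subsets of animals in the alternatives, as symbols in a figure, and in the closing section.

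The deposited values are raw counts of reads per gene, whole numbers that were not normalized. Per the submitters' processing notes, reads were examined with FastQC, aligned with HISAT2 to the build ARS-UCD1.2 and counted with featureCounts, and edgeR was used. The roles of these tools are read from their usual function, and their versions, the annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Without the strand setting, overlapping and antisense genes cannot be told apart, and counts of near-identical paralogs such as the myosin heavy chains are uncertain. Per the labels, total RNA was extracted, treated with DNase and column purified before standard library preparation. The table held 18078 gene rows, of which 16189 were typed as protein coding and 1889 had no type; 2578 rows had no symbol, 25 symbols had been turned into date numbers by a spreadsheet, and 193 rows held no read. Gene names were taken from the table itself; 54 symbols stood on more than 1 row, and the row with the most reads was used. The reference table supplied, of the assembly ARS-UCD2.0, matched 0 of the identifiers, and because its build differs no coordinates are given. None of the 13 mitochondrially encoded genes was found under the names fixed, so their share was not computed, and the alternative that leaves them and ribosomal RNA out of the library size was not run.

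Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 2 groups (minimum count 10, minimum total 15), which left 12187, and libraries were scaled by the trimmed mean of M-values. The difference between groups was tested with the quasi-likelihood F test at default settings without covariates, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Ratios are fold changes of the fit, restricted over control; their standard error is the log2 fold change divided by the root of F, and 95% intervals use the t distribution of the fit. CPM values are scaled in the same way. For each of 37 gene lists, the mean log2 CPM (prior count 2) of its tested members was taken per animal, and the group difference was tested with a two-sided exact permutation test over all 3432 assignments of 7 of the 14 animals, whose smallest p is 0.000583; the 95% interval holds the shifts this test does not reject. Lists with fewer than 3 tested members were left out, which left 34. Shares of counts, principal components and the median log2 ratio of the SDs per gene were tested by the same permutations. The smallest chi-square per degree of freedom between the counts of any 2 libraries was 12, so no library was a copy or a resequencing of another. This value cannot tell a second preparation of the same RNA from a sample of another animal.

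The genes named were set by a rule written before the data were examined: the 5 genes with a symbol and the smallest p in each direction when fewer than 5 passed, list members past the threshold adjusted over the list alone, of which there were 0, and MSTN, IGF1, IGF2, PAX7, MYH7, PPARG, FABP4 and FBXO32. The list members given as examples for the comparisons between diets were chosen after the data were seen, from the 2 most abundant tested members of each list, without regard to the group difference. Apart from these, MYH11, LMOD1, KLF15, ANGPTL4 and PDK4 were named for their ratios or p-values after these were seen. ISG15, MYH3, MYH4 and the genes named by title letter, in the closing section, were chosen after their values were seen. So was the range of MYH4 given beside the fast fibre list.

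Depth ran from 13631018 to 17325779 counts per animal. The common biological coefficient of variation was 0.190 and the 95% intervals reached 0.26 log2 to either side of the fold change at the median. The test was tested on simulated data: in 5 runs, counts of the 12187 genes were drawn with the means, dispersions and library sizes of these 14 libraries, with 200 genes changed per run. For 7 against 7 animals, the threshold was passed by 2.4% of 250 genes changed 1.2-fold, 49.2% of 250 changed 1.5-fold, 82.4% of 250 changed 2-fold and 94.8% of 250 changed 3-fold, and by 28 of 59935 unchanged genes. Intervals covered the true value for 95.6% of changed genes. In unchanged simulated data 0 genes passed in each run. Changes of all sizes were simulated together, so the larger ones eased the adjustment for the smaller ones. Genes were also drawn independently of each other. Unchanged simulated data had 571 to 605 genes at an edgeR unadjusted p under 0.05, and 100 splits of the real animals 271 to 1024. The percentages passing are therefore not detection rates for a few changed genes in these animals. After removal of the group means from the real scores, a shift of 0.25 log2 added to every list brought 18 of 34 lists past the threshold, a shift of 0.5 brought 29 and a shift of 1 brought 33. All lists were shifted at once, which eases the adjustment, and the difference equalled the shift exactly. These counts are therefore not detection rates for a change in 1 or a few lists.

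The alternatives were relative log expression, upper quartile and library size scaling; no filter and a filter of 1 CPM in 7 samples; DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), edgeR's exact test and its robust fit; the first letter, the last letter or 1 surrogate variable (sva 3.50.0) as a covariate; only titles starting with Y; an adjusted p under 0.1; and leaving out each animal in turn. For lists they were camera with a preset and an estimated correlation, fry, and the median over members; for the SDs, genes above a mean log2 CPM of 1 and the median absolute deviation. Only titles ending in A, and leaving out control 7, restricted 4 and restricted 7, were added after seeing the data.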

Results

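Transcript levels were measured by RNA sequencing in the longissimus dorsi, the long muscle of the back, of 14 female cattle at postnatal day 485. The dams of 7 animals had received 100% of their nutrient requirement from day 158 of gestation until birth (control), and the dams of the other 7 had received less over the same period (restricted). The labels do not agree on the restricted level. The description of the series design states 70% and the treatment protocol of the samples states 50%, so the group is called restricted here without a percentage. The offspring were managed alike, with feed offered ad libitum from day 301. Each sample was 1 animal, and the labels do not say whether animals shared a dam or a sire. Total counts per animal ranged from 13631018 to 17325779, with a mean of 15708000 ± 1186000 (SD, n = 7) in controls and 15924000 ± 831190 (SD, n = 7) in restricted offspring (two-sided exact permutation p = 0.705). The counts were dominated by contractile and glycolytic transcripts. MYH1, a fast myosin heavy chain, held 5.57% ± 0.446 (SD, n = 14) of all counts, the skeletal actin ACTA1 4.38% ± 0.494, and the glycolytic enzyme ALDOA 3.0% ± 0.24.

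The first comparison asked which genes differed in the muscle of adult offspring according to the feeding of the dam in later gestation. By edgeR's quasi-likelihood test no gene passed the adjusted threshold in either direction, with 518 at an unadjusted p under 0.05. Of the other tools, DESeq2 passed 1 gene, MTSS1L, lower in restricted offspring with an adjusted p of 0.0347, and limma's voom and edgeR's exact test passed 0. No other gene named here was called higher or lower by any of these tools. In the direction of higher values in restricted offspring, the smallest p-values belonged to PDLIM3, a Z-disc protein that binds actinin, and PREP, a prolyl endopeptidase. They also belonged to S100A16, a calcium-binding protein, CAMK4, a calcium and calmodulin dependent kinase, and CDKAL1, a tRNA-modifying enzyme. PDLIM3 (ENSBTAG00000017183) was at 2465 ± 174 CPM, counts scaled to the library size, in controls and 3085 ± 336 CPM in restricted offspring (SD, n = 7 each), a 1.25-fold ratio with a 95% interval of 1.12 to 1.40. In the opposite direction they belonged to MTSS1L, GULP1, an adaptor for the engulfment of dying cells, CRACR2B, a regulator of store-operated calcium entry, ZNF75A and MISP3. MTSS1L (ENSBTAG00000009358) was at 6.82 ± 1.5 CPM in controls and 4.16 ± 0.402 CPM in restricted offspring, a ratio of 0.61 with an interval of 0.499 to 0.746.

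CAMK4 was at 1.47 ± 0.412 CPM in controls and 2.77 ± 0.960 CPM in restricted offspring, a ratio of 1.88 with an interval of 1.34 to 2.64. GULP1 was at 1.30 ± 0.269 and 0.624 ± 0.180 CPM, a ratio of 0.481 with an interval of 0.351 to 0.659. The ratios of PREP (1.23), S100A16 (1.25), CDKAL1 (1.23), CRACR2B (0.669), ZNF75A (0.561) and MISP3 (0.748) were closer to 1 than those of CAMK4 and GULP1. For each of these 10 genes, picked for their small p, all 7 restricted animals lay on 1 side of the control median. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, unadjusted p-values were 7.66e-05 for MTSS1L, 0.000139 for GULP1 and 0.000715 for PDLIM3, and the smallest adjusted p over the 12187 genes tested was 0.847, shared by MTSS1L and GULP1. GULP1, ZNF75A and CAMK4 rested on low counts, with means of 15.3, 13.1 and 33.6 reads per animal.

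**Figure D1:**
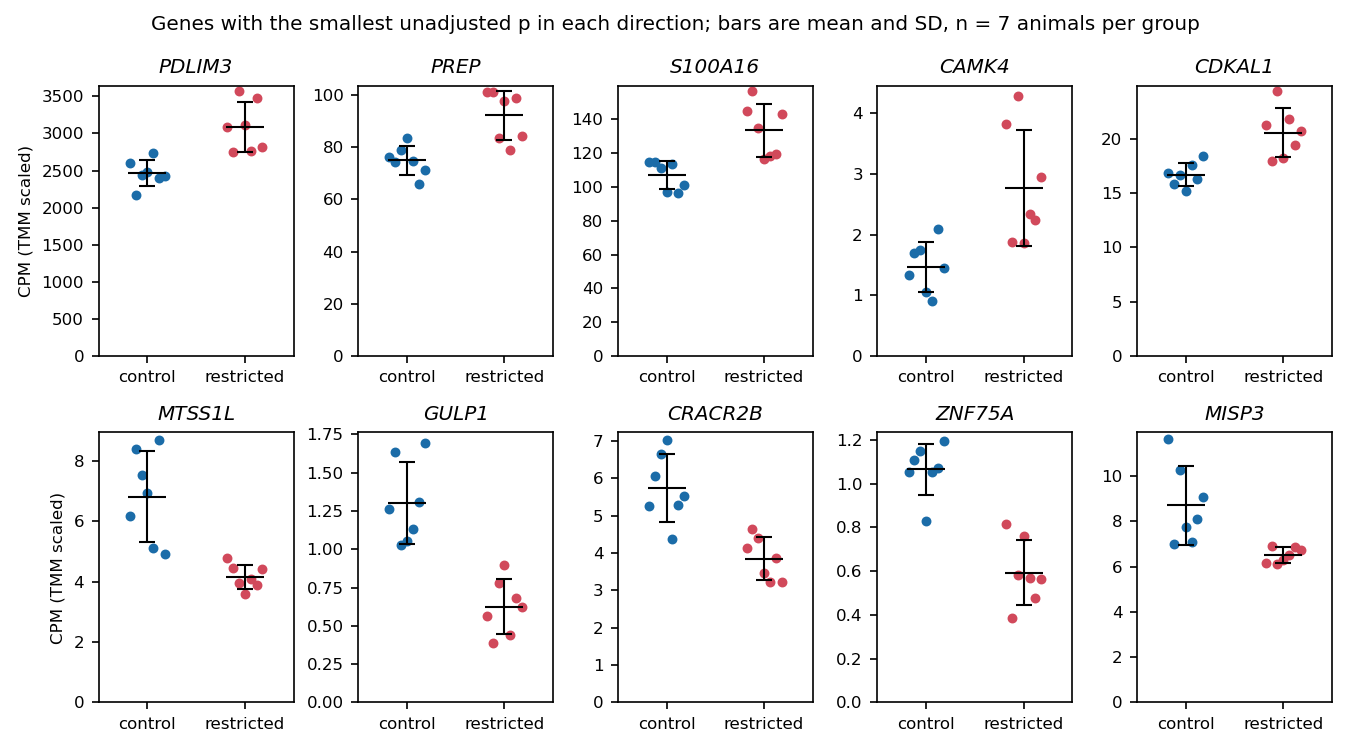
CPM (linear axis from 0, scaled by the trimmed mean of M-values) of the 5 genes with the smallest unadjusted p in each direction, for 7 control and 7 restricted animals; points are animals and bars are the mean and SD. MTSS1L averaged 6.82 CPM in controls and 4.16 CPM in restricted offspring, and none of the 10 genes passed the adjusted threshold by edgeR's quasi-likelihood test, while MTSS1L passed by DESeq2 (adjusted p = 0.0347).

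None of the genes of muscle growth and fat deposition chosen before the data were examined passed the threshold. MSTN, which encodes the growth inhibitor myostatin, was at 22.2 ± 6.69 CPM in controls and 26.1 ± 6.31 CPM in restricted offspring (SD, n = 7 each), a ratio of 1.18 with a 95% interval of 0.908 to 1.53. PAX7, the marker of satellite cells, was at 0.822 ± 0.333 and 1.11 ± 0.262 CPM, a ratio of 1.34 with an interval of 0.894 to 2.0. PAX7 rested on low counts, with a mean of 15.3 reads per animal and 4 reads in control 2. The ratio was 1.05 for the growth factor IGF2 (0.825 to 1.34), 0.946 for the slow myosin MYH7 (0.744 to 1.2) and 0.963 for FBXO32, a ubiquitin ligase of muscle atrophy (0.714 to 1.30). For the adipocyte genes PPARG and FABP4 the ratios were 0.965 (0.639 to 1.46) and 0.933 (0.464 to 1.88), so FABP4 levels in this muscle left room for a change of more than 1.5-fold either way. Leaving out 1 animal moved the log2 fold change of each of these 7 genes by over 1.5 times. That of MSTN went from 0.234 to 0.379 without control 6 and to 0.126 without restricted 7, that of PAX7 from 0.42 to 0.254 without control 2, and those of the other 5 changed sign in at least 1 such fit. With all animals those of the other 5 lay from -0.1 to 0.073, so close to 0 that a small shift also reaches this ratio. The smallest unadjusted p among these 7 genes was 0.146, for PAX7, by edgeR. IGF1 was below the filter on low counts, with 2 to 13 reads per animal, and was not tested.

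Over all genes, edgeR's quasi-likelihood test placed 0 of 12187 past an adjusted p of 0.05, and 518 had an unadjusted p under 0.05 (264 higher and 254 lower in restricted offspring), against 609.4 expected by chance. DESeq2 placed 1 gene past the threshold, MTSS1L, with an adjusted p of 0.0347, and had 528 genes at an unadjusted p under 0.05. Limma's voom with sample quality weights placed 0 genes past it, with 586 at an unadjusted p under 0.05, and edgeR's exact test 0, with 446. Over its alternatives the adjusted p of MTSS1L ran from 0.0347 to 1. The 95% intervals of 11615 genes (95.31%) excluded a 2-fold difference in both directions. Those of 9487 genes (77.85%) excluded a 1.5-fold difference in both directions. Among the 6647 genes with a mean above 10 CPM, 94.58% excluded a 1.5-fold difference. Without control 7, restricted 4 and restricted 7, which lay farthest out on the first 2 principal components (a choice made after seeing the data), 0 of 12270 genes passed and 612 had an unadjusted p under 0.05.

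The second comparison asked whether groups of functionally related genes moved together, with 37 lists fixed before the data were examined. No list of contractile or growth genes passed the test. The fast fibre list lay 0.14 log2 higher in restricted offspring (95% interval -0.070 to 0.35, two-sided exact permutation p = 0.146), with 14 of its 15 members on the positive side. Its difference ran from 0.033 to 0.192 over its 20 alternatives. The slow fibre list lay at -0.084 (-0.55 to 0.38, permutation p = 0.678), with 4 of 14 positive. MYH1 was at 55120 ± 4992 CPM in controls and 56560 ± 6118 CPM in restricted offspring (SD, n = 7 each). MYH2, another fast myosin, was at 14020 ± 3070 and 16140 ± 4146 CPM, and MYL2, a slow light chain, at 5683 ± 1422 and 5910 ± 1071 CPM. Myogenic regulators and developmental isoforms lay at 0.16 (-0.18 to 0.51, permutation p = 0.304), and at 0.254 without control 4 and 0.089 without restricted 2, with MYF6 at 113.1 ± 23.04 and 118.0 ± 21.61 CPM. Calcium handling and excitation-contraction coupling lay at -0.018 (permutation p = 0.615; -0.067 with library size scaling, permutation p = 0.0361), and muscle atrophy and autophagy at -0.054 (permutation p = 0.563). The difference was 0.040 for calpain and cathepsin proteolysis (permutation p = 0.424), and 0.014 for IGF, insulin and growth signalling (-0.037 to 0.067, permutation p = 0.592). Reads of the myosin heavy chain genes can be shared between near-identical paralogs, so their single values are uncertain. The fast fibre, slow fibre and myogenic lists average over such genes with equal weight, so this uncertainty enters these lists too. MYH4, a member of the fast fibre list, ran from 4.35 to 9.57 log2 CPM between animals.

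Among metabolic lists, cholesterol synthesis lay highest, at 0.18 log2 (95% interval -0.032 to 0.37, two-sided exact permutation p = 0.0863), with 18 of 20 members positive and 5 at an unadjusted p under 0.05. It lay at 0.248 without restricted 4 (exact permutation p = 0.00350, adjusted 0.119), at 0.226 without the 3 libraries named above (exact permutation p = 0.00866) and at 0.072 with only titles ending in A (exact permutation p = 0.532), and the last 2 of these choices were made after seeing the data. HMGCS1, an early enzyme of that pathway, was at 36.9 ± 2.85 CPM in controls and 43.0 ± 7.46 CPM in restricted offspring (SD, n = 7 each), while FDFT1, the squalene synthase, was at 101.5 ± 13.5 and 91.5 ± 24.2 CPM. Fatty acid and triglyceride synthesis lay at 0.16 (-0.16 to 0.51, permutation p = 0.35), and at 0.045 without restricted 7, with the desaturase SCD at 319.7 ± 124.7 and 416.5 ± 298.6 CPM. Glycolysis and glycogen lay at 0.050 (-0.031 to 0.13, permutation p = 0.17) with 21 of 25 members positive, and from 0.001 to 0.068 over its 20 alternatives. The TCA cycle with nuclear-encoded oxidative phosphorylation lay at 0.067 (-0.10 to 0.23, permutation p = 0.393) with 47 of 56 positive, and at 0.019 without restricted 1. Fatty acid oxidation lay at 0.060 (permutation p = 0.441), antioxidant and detoxification genes at 0.050 (permutation p = 0.457) and hypoxia and angiogenesis at 0.025 (permutation p = 0.71).

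No list of markers of the other cell types a muscle sample can hold passed the test. For adipocytes the difference was 0.017 log2 (95% interval -0.74 to 0.89, two-sided exact permutation p = 0.97). It depended on single animals, at -0.271 without control 6 and 0.152 without control 3. The differences were -0.086 for fibroblasts and fibro-adipogenic progenitors (permutation p = 0.607) and -0.063 for extracellular matrix (permutation p = 0.708). They were -0.068 for endothelium (permutation p = 0.49), -0.15 for smooth muscle and pericytes (-0.33 to 0.030, permutation p = 0.0921) and 0.042 for macrophages and monocytes (permutation p = 0.854). They were 0.094 for T and NK cells (permutation p = 0.774) and 0.062 for nerve, Schwann cell and neuromuscular junction (permutation p = 0.668), which lay at -0.43 by the median of its members (permutation p = 0.0169, not past after adjustment). In the adipocyte list 11 of 16 members were negative. Its most abundant members GPD1 and PLIN4, which muscle fibres also express and which therefore say little about adipocytes, were at 1382 ± 144.4 and 233.8 ± 33.5 CPM in controls and at 1423 ± 170.8 and 236.5 ± 39.5 CPM in restricted offspring (SD, n = 7 each). The matrix gene COL3A1 was at 259.8 ± 92.8 and 267.5 ± 116.6 CPM, and the endothelial gene VWF at 64.4 ± 12.2 and 56.9 ± 13.3 CPM. The smooth muscle list had a permutation p of 0.0309 without control 3 and 0.0402 without restricted 3, and 10 of 12 of its members were negative. Its most abundant members ABCC9 and RGS5, with ratios of 1.05 and 1.01, were the 2 positive ones. The lowest ratios were 0.742 for MYH11 and 0.758 for LMOD1. By edgeR their unadjusted p-values were 0.0588 and 0.0384, and 0.3525 for both when adjusted over the list alone. B and plasma cell and erythroid markers had 1 and 2 tested members and were not tested as lists.

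No immune, stress or regulatory list passed the test between the diets. The interferon response list lay at 0.23 log2 with an interval of -1.15 to 1.64 (two-sided exact permutation p = 0.763). Control 7, restricted 4 and restricted 7 scored 3.60, 3.12 and 4.34 on mean log2 CPM and the other animals 0.64 to 2.04. MX1, an antiviral GTPase of that list, was at 11.1 ± 15.9 CPM in controls and 19.9 ± 30.9 CPM in restricted offspring (SD, n = 7 each). MHC class I and II lay at 0.083 (permutation p = 0.548), and inflammatory cytokines and acute phase at -0.10 (permutation p = 0.515). Immediate early genes lay at -0.049 (permutation p = 0.853), heat shock response at 0.0050 (permutation p = 0.962), and integrated stress and unfolded protein response at 0.14 (permutation p = 0.41), or 0.026 without restricted 1. The glucocorticoid target list lay at -0.022 (permutation p = 0.907), with DDIT4, an inhibitor of mTOR signalling, at 332.7 ± 65.9 and 227.9 ± 115.8 CPM. Of its 15 tested members, 4 had an edgeR unadjusted p under 0.05, in both directions. Among them the ratio was 0.744 for KLF15, 2.08 for ANGPTL4 and 3.33 for PDK4, and none passed after adjustment. The SD of its score was 0.119 in controls and 0.447 in restricted offspring, where restricted 4 and restricted 6 scored 6.17 and 5.87. Circadian clock genes had the smallest p of the 34 lists, at -0.10 log2 (-0.20 to -0.0010, permutation p = 0.0490), with 11 of 17 members negative. Its p was 0.05 or more in 10 of the 14 fits without 1 animal (exact permutation p from 0.00874 to 0.0938). By the same test it was 0.052 with relative log expression scaling, 0.0779 with only titles starting with Y, 0.413 with only titles ending in A and 0.94 by the median of its members. It was 0.0169 with library size scaling and 0.0325 without the 3 libraries. The difference ran from -0.15 to -0.01 over these alternatives. Imprinted genes lay at -0.0070 (permutation p = 0.939), DNA methylation and histone modifiers at -0.023 (-0.094 to 0.045, permutation p = 0.462), cell cycle genes at 0.059 (permutation p = 0.481) and ribosomal proteins at 0 (-0.17 to 0.17, permutation p = 0.994).

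By the exact permutation test, 0 of the 34 lists with at least 3 tested members passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.965), and 1 had an unadjusted p under 0.05. No list member passed over all genes tested, and 0 passed when adjusted over the list alone. Leaving out 1 animal moved the difference of 29 of the 34 lists by over 1.5 times. The other 5 were fast fibre, cholesterol synthesis, glycolysis and glycogen, smooth muscle and circadian clock. The 29 include lists so near 0 that a small shift reaches this ratio. Ribosomal proteins, at 0, were moved by each of the 14 animals. The intervals of 30 lists excluded a 1.5-fold difference in both directions, leaving out adipocyte, T and NK cell, interferon and immediate early genes. Camera with a preset correlation of 0.01 placed 6 lists past the threshold, of which smooth muscle lay on the negative side and the others on the positive side. Their adjusted p was 5.65e-05 for cholesterol synthesis, 0.000329 for the TCA cycle and oxidative phosphorylation, 0.00545 for fast fibre, 0.0194 for glycolysis, and 0.0486 for both fatty acid synthesis and smooth muscle. None held with an estimated correlation: adjusted p = 0.877 for cholesterol synthesis, fast fibre, glycolysis, fatty acid synthesis and smooth muscle, and adjusted p = 0.915 for the TCA cycle list. The directional test of fry placed 0 lists past the threshold, with 0 at an unadjusted p under 0.05.

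**Figure D2:**
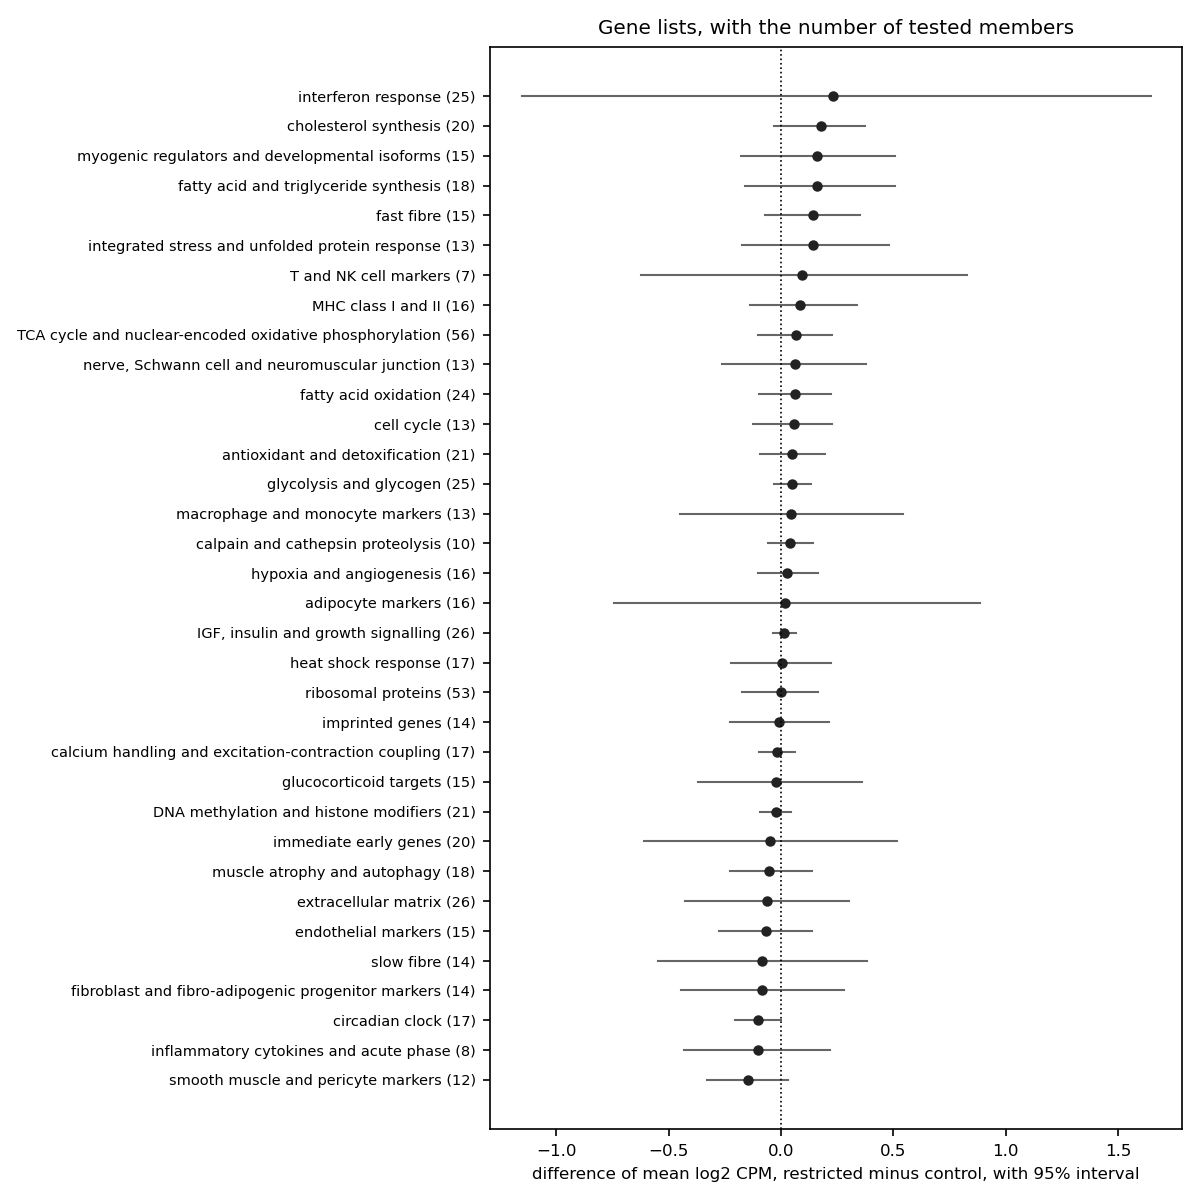
Difference of the mean log2 CPM of 34 gene lists, restricted minus control, with 95% intervals from the exact permutation test over 7 control and 7 restricted animals; numbers in brackets are tested members. The interval of the interferon response list was the widest, from -1.15 to 1.64, and the circadian clock list was the list whose interval excluded 0, from -0.20 to -0.0010, before adjustment; its p was 0.05 or more in 10 of the 14 fits without 1 animal.

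The third comparison asked whether the libraries differed in composition or spread. The 10 most abundant genes, led by MYH1, ACTA1 and ALDOA, held 22.8% ± 0.998 of counts in controls and 23.5% ± 0.722 in restricted offspring (SD, n = 7 each; two-sided exact permutation p = 0.129, adjusted over 3 shares 0.386). Ribosomal protein genes held 1.34% ± 0.150 and 1.29% ± 0.0787 (exact permutation p = 0.531, adjusted 0.538), and erythroid genes 0.000335% ± 0.000181 and 0.000561% ± 0.000645 (exact permutation p = 0.538, adjusted 0.538). The first principal component, on which restricted 7 and control 7 were at 34.1 and 24.4, held 13.9% of the variance and did not separate the diets (exact permutation p = 0.967). The median Spearman rho of log2 CPM was 0.980 within groups and 0.981 between them. Over the tested genes, the SD between animals was 1.08-fold larger in restricted offspring at the median (log2 ratio 0.11, exact permutation p = 0.101), and 6951 genes (57.04%) had the larger SD there. Without control 3 the ratio was 1.12-fold with an exact permutation p of 0.0216, and without restricted 4 it was 1.04-fold with p = 0.430 by the same test, so leaving out control 3 changed the side of the threshold.

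**Figure D3:**
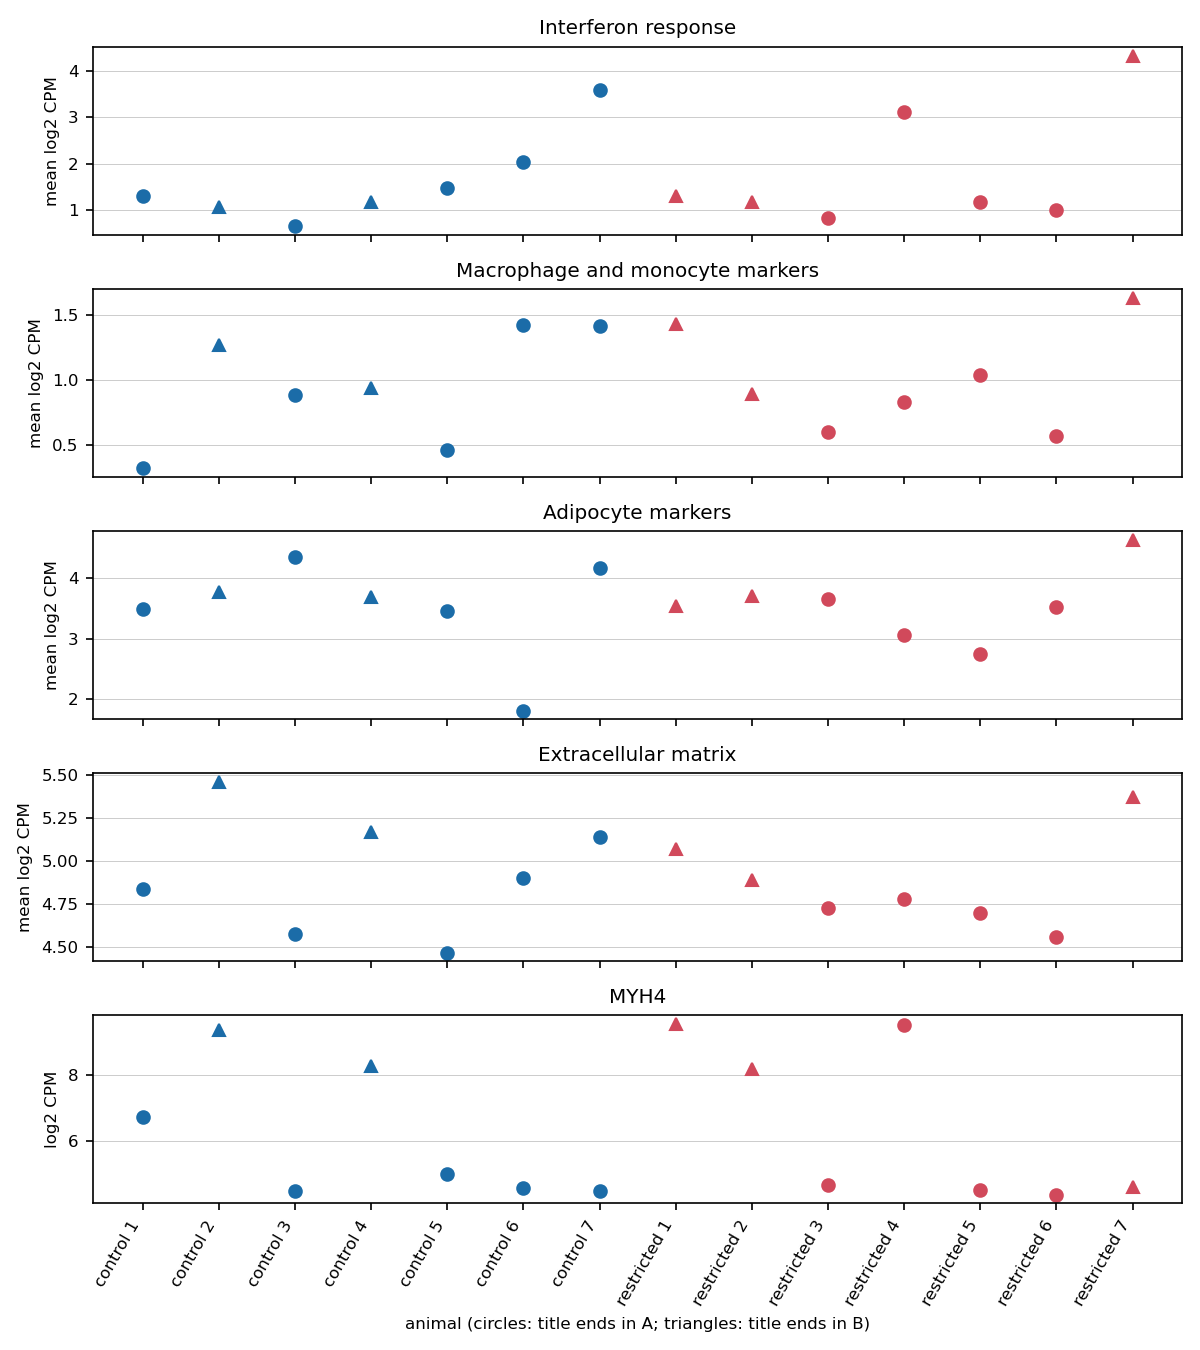
Values per animal (mean log2 CPM of the list members, or log2 CPM for MYH4) in 7 control animals (blue) and 7 restricted animals (red); circles mark sample titles ending in A and triangles those ending in B, letters whose meaning the labels do not give. Interferon response scores were 3.60 in control 7, 3.12 in restricted 4 and 4.34 in restricted 7, against 0.64 to 2.04 in the other animals.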

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

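All tests of explanations in this part were chosen after the results were seen. In 9 of 110 groups of 7 values, 1 animal lay far from the rest of its group (a gap to the nearest animal above Dixon's critical share of the range), where chance gives 5.5. Control 6 had the lowest adipocyte marker score of the controls, 1.81 against 3.46 for the next on mean log2 CPM, their lowest fatty acid and triglyceride synthesis score, 4.14 against 4.60, and their highest cell cycle score, 2.09 against 1.80. Restricted 1 had the highest score of its group for MHC class I and II, 5.11 against 4.64, and for the TCA cycle and oxidative phosphorylation, 8.14 against 7.89. Control 4 had the highest score of the controls for myogenic regulators and developmental isoforms, 4.91 against 4.43, and their lowest log2 CPM of ZNF75A, -0.0629 against 0.237. Control 5 had the lowest IGF, insulin and growth signalling score of the controls, 4.72 against 4.80. Restricted 3 had the highest share of its group in erythroid genes, 0.00198% against 0.00057%.

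Interferon-stimulated genes were high in control 7, restricted 4 and restricted 7, where the list lay 2.37, 1.90 and 3.12 log2 above the median of the 14 animals; ISG15, a ubiquitin-like antiviral protein chosen after its values were seen, was at 16.9, 12.4 and 35.4 CPM there and at 0.389 to 2.92 CPM in the others. A rise of leukocyte markers as large as that of the interferon list is argued against. The highest rise of the macrophage or the T and NK cell list among the 3 animals was 0.72 log2, below the smallest interferon rise. Relative to the median, these lists lay at 0.72 and 0.70 in restricted 7 and at 0.50 and 0.33 in control 7. In restricted 4 they lay at -0.08 and -0.82. A smaller rise of leukocytes in restricted 7 and control 7 stays open. MRC1 and LAPTM5, the most abundant macrophage markers, averaged 7.78 and 17.0 CPM in controls. The next, CSF1R, averaged 2.93 CPM there, and IL2RB, the most abundant T and NK cell marker, 3.01 CPM. Scaling is argued against as well, since the log2 scaling factors of the 14 libraries spanned 0.221. The diet of the dam stays open (exact permutation p = 0.763, interval -1.15 to 1.64), because the spread between animals is too wide for 7 against 7, although 1 of the 3 animals was a control. An antiviral response of those animals at slaughter is a candidate explanation that nothing in the labels allows to be tested. The MHC class I and II list did not rise with the interferon list there. It lay 0.04, 0.01 and 0.15 log2 above the median in control 7, restricted 4 and restricted 7.

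The fast myosin gene MYH4 was at 675 and 310 CPM in control 2 and control 4, at 759, 294 and 751 CPM in restricted 1, 2 and 4, at 105 CPM in control 1, and at 20.3 to 31.4 CPM in the other 8 animals. MYH3, the embryonic myosin, was at 38.0 to 80.8 CPM in the same 5 animals and at 5.01 to 8.56 CPM in the others, except restricted 6, which had 72.5 CPM of MYH3 and 20.3 CPM of MYH4. Reads leaking from MYH1 and MYH2 at a fixed rate are argued against, since the ratio of MYH4 counts to MYH1 plus MYH2 counts differed 38.0-fold between the highest and the lowest animal; such reads could still make up the low level. The diet of the dam stays open (exact permutation p = 0.781; difference 0.37 log2, interval -2.37 to 2.97). A difference in sequence between animals that moves reads between the myosin genes was not tested, since reads were not analysed here. Whether the levels of MYH4 and MYH3 reflect genotype or fibre type is a hypothesis without a test here.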

How the results depend on the processing

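The count of 0 genes past the adjusted threshold held under each alternative chosen before the data were examined except DESeq2, which gave 1 gene, lower in restricted offspring (MTSS1L); the cause was not tested. Among the 2 alternatives chosen after seeing the data, only titles ending in A (fewer samples) gave 1 gene, higher in restricted offspring, ENSBTAG00000025385, with an adjusted p of 0.0458, and leaving out 3 libraries gave 0. Leaving out each animal in turn gave 0 genes, with 472 to 692 at an unadjusted p under 0.05. Camera with a preset correlation gave 6 lists and an estimated correlation 0. The median log2 ratio of SDs ran from 0.0519 without restricted 4 to 0.163 without control 3, where it passed. The alternative without mitochondrial and ribosomal RNA genes was not run, as no such gene was found under the names fixed. Replicate numbers follow sample order, so no fit with them as a block was made. Depth limits genes near the filter, such as IGF1 with 2 to 13 reads.

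Of the log2 fold changes of the named genes under alternatives, 472 kept their direction and side of the threshold, 1 passed it (MTSS1L) and 18 changed sign; of the list differences 589 kept both and 91 changed sign, all in values that passed no threshold. The cause of these sign changes was not tested. By gene they were PPARG 0.042 and FABP4 0.205 with limma. With the median over members the lists were slow fibre 0.001, muscle atrophy 0.096, IGF and insulin signalling -0.001, ribosomal proteins -0.027 and inflammatory cytokines 0.174. They were also nerve and junction -0.432, heat shock response -0.008, integrated stress -0.074, glucocorticoid targets 0.155, chromatin modifiers 0.086 and calcium handling 0.054. With library size scaling they were calpain -0.008, IGF and insulin signalling -0.034, adipocyte -0.029, ribosomal proteins -0.048, macrophage -0.003, heat shock response -0.043 and hypoxia -0.023. With only titles starting with Y the values were IGF2 -0.029, ribosomal proteins -0.047, macrophage -0.105, T and NK cell -0.191, immediate early genes 0.115 and glucocorticoid targets 0.005. With only titles ending in A they were MSTN -0.002, FBXO32 0.022, muscle atrophy 0.026, calpain -0.028, adipocyte -0.217, TCA cycle -0.028, ribosomal proteins -0.068, endothelial 0.019 and macrophage -0.133. They were also T and NK cell -0.156, interferon response -0.285, immediate early genes 0.394, integrated stress -0.04, glucocorticoid targets 0.135, chromatin modifiers 0.003, cell cycle -0.054, hypoxia -0.002 and antioxidant -0.038. Without the 3 libraries they were PPARG 0.028, IGF and insulin signalling 0, fatty acid oxidation -0.027, interferon response -0.193 and imprinted genes 0.092. Leaving out each animal in turn gave ranges of MYH7 -0.166 to 0.011, FABP4 -0.452 to 0.205, IGF2 -0.005 to 0.162, FBXO32 -0.162 to 0.078 and PPARG -0.233 to 0.17 by gene. By list they were ribosomal proteins -0.026 to 0.059, macrophage -0.064 to 0.119, T and NK cell -0.09 to 0.224, heat shock response -0.037 to 0.065, extracellular matrix -0.147 to 0.024, fibroblast -0.16 to 0.008 and immediate early genes -0.196 to 0.08. The others were imprinted genes -0.066 to 0.039, glucocorticoid targets -0.151 to 0.055, IGF and insulin signalling 0 to 0.023, hypoxia -0.016 to 0.048, adipocyte -0.271 to 0.152, nerve and junction -0.008 to 0.138, MHC -0.01 to 0.125 and interferon response -0.184 to 0.565. The difference in the ribosomal share ran from -0.0659 to 0.00341 and in the erythroid share from -9.75e-06 to 0.000299 percentage points.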

Other observations

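The tests by title letter and the choice of the genes named in this part were made after the results were seen, as were the tests of the genes with a wide range. Genes of the extracellular matrix had higher mean levels in the 5 animals whose titles end in B than in the 9 ending in A, letters whose meaning the labels do not give. The list lay 0.45 log2 higher (95% interval 0.19 to 0.70, two-sided exact permutation p = 0.00350 over 2002 assignments), which did not pass after adjustment over the 34 lists (adjusted p = 0.119). COL1A1 and COL3A1, chains of fibrillar collagen, were at 61.7 ± 18.8 and 208.3 ± 42.5 CPM in A and at 118.9 ± 31.6 and 363.3 ± 102.2 CPM in B (SD, n = 9 and 5). LUM, a proteoglycan of collagen fibrils, was at 17.8 ± 2.25 and 29.2 ± 6.68 CPM. SPP1, osteopontin, was at 0.539 ± 0.455 and 4.90 ± 2.99 CPM and had the smallest adjusted p by edgeR, 0.0720; these genes were chosen after their values were seen. By edgeR, 0 genes passed between the letters and 740 had an unadjusted p under 0.05, and no other tool was run. Between first letters R and Y (3 and 11 animals) 0 passed, with 458.

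More fibroblasts in the samples ending in B may account for this, as the fibroblast marker list lay 0.376 higher there too (exact permutation p = 0.0205, adjusted 0.174). The macrophage, T and NK cell and adipocyte lists lay at 0.39, 0.63 and 0.51 (exact permutation p = 0.0809, 0.0535 and 0.200). The fibroblast list itself holds matrix genes such as LUM, named above. It therefore cannot separate more fibroblasts from more matrix transcripts per fibroblast. The difference was not limited to matrix and fibroblast genes. Of the 34 lists, 7 had an unadjusted p under 0.05 by exact permutation and 0 passed after adjustment. Besides matrix and fibroblasts, these were fatty acid and triglyceride synthesis at 0.343 (exact permutation p = 0.0130), MHC class I and II at 0.249 (p = 0.0130), myogenic regulators at 0.321 (p = 0.0390), integrated stress at 0.307 (p = 0.0400) and cholesterol synthesis at 0.214 (p = 0.0440), and no test tied them to fibroblasts. Unequal shares of the diets are argued against, since the difference was 0.52 within controls and 0.418 within restricted offspring. Beyond fibroblasts and the diets no biological explanation was tested, because the labels do not say what the letter stands for. MYH4 lay 2.65 log2 higher in animals ending in B (exact permutation p = 0.0365, adjusted over 6 myosin heavy chain genes 0.219), with restricted 7 in B at 4.58 and restricted 4 in A at 9.55 log2 CPM against this trend.

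In 24 genes, 15 of them with a symbol, log2 CPM spanned at least 5 with at least 3 animals near each end of the range. ULBP13, a ligand of immune receptors, ran from -2.98 to 6.39 with 5 animals near the low end and 9 near the high end. The notch ligand DNER ran from -2.04 to 5.96 with 5 and 9, and the class II genes BOLA-DQA5 and BOLA-DQA1 from -2.98 to 3.90 and from 0.52 to 5.78. Exact permutation p-values between diets were 0.349, 0.681, 0.651 and 0.196 for these 4 genes. In ULBP13 and BOLA-DQA5 the low end, -2.98, is the value that no reads take under the prior count of 2. Their span therefore sets no reads against some reads, and its size depends on that prior count. PDK4, a kinase that restrains glucose oxidation, was at 87.1 ± 50.7 CPM in controls and 290.0 ± 443.2 CPM in restricted offspring (SD, n = 7 each), an edgeR ratio of 3.33 with an unadjusted p of 0.0339 that did not pass; it was chosen after its values were seen. Restricted 6 and restricted 4 were at 1200 and 547 CPM and the other restricted animals at 33.3 to 74.0 CPM. By edgeR's quasi-likelihood test the ratio was 1.57 without restricted 6 (unadjusted p of 0.294) and 2.83 without restricted 4 (unadjusted p of 0.0697), and the unadjusted p was also 0.05 or more without control 5, control 6 or control 7.

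Chance cannot be excluded for the number of genes at an unadjusted p under 0.05 between diets. Of 100 splits of the 14 animals into 7 and 7, the real one included, 72 gave at least as many genes as the real 518 at an unadjusted p under 0.05, and the highest of the other splits gave 1024. The count past the adjusted threshold decides nothing here, since no split can give fewer than the real 0 and so 100 of 100 gave as many, with 25 in the highest of the others. The split with 25 genes held 4 restricted animals and 3 with titles ending in B among the 7 animals of 1 side, so it followed neither. So many calls in 1 split can come from a structure among the animals, but 2 of the 100 splits gave any gene past the threshold, as chance can at 0.05, and no test here separates these.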
